A study of Etheostoma caeruleum with 31 samples.

How the data were processed

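RNA from the testes of adult male rainbow darters (Etheostoma caeruleum), a small freshwater fish, was measured on 1-colour oligonucleotide microarrays. The fish were caught in the Grand River, Ontario, in 5 calendar months, and each month stands for a stage of the annual reproductive cycle. The stages are spawning (month 5 of 2011, 7 arrays), post-spawning (month 8 of 2011, 6 arrays), recrudescence (month 10 of 2011, 5 arrays), developing (month 1 of 2012, 6 arrays) and pre-spawning (month 3 of 2012, 7 arrays). Per the labels, total RNA was extracted with Trizol and labelled with Cy3 by the Agilent 1-colour protocol, and the arrays of a stage are biological replicates. Stage and calendar month coincide, so that season, water temperature and reproductive state cannot be told apart from each other, and each stage comes from a single collection.

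Per the file headers, the arrays were scanned on an Agilent scanner and extracted with Agilent Feature Extraction 10.7.1.1. The deposited scanner output gives an intensity per spot on a linear scale, already corrected for background within the array and not normalised between arrays. A table of the authors' processed values covers the same arrays on a log2 scale. The normalisation of the authors' log2 table is not given in the sources used here. Within every array its ranks equalled those of the scanner intensity (Spearman rho of 1), and its sorted values differed between arrays by 0.0423 on average on the log2 scale, as they would after quantile normalisation. That table holds 15171 of the 15208 non-control spots, and it served only as an alternative.

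The main values were computed from the scanner intensities. The log2 of each spot's processed intensity was taken relative to the array's 75th percentile of it. Spots carrying Agilent's outlier flags (426 over all arrays) were removed, and the spots of a probe were averaged. No non-control spot was saturated. The 9041 probes comprised 2897 with 1 spot, 6121 with 2 spots and 23 with 3 spots. A probe counted as well above background on an array when at least a share of 0.5 of its spots did. The 8638 probes well above background on at least 5 of the 31 arrays were tested, and 403 dimmer probes (4.46%) were left out. For arrays, the number of replicates limits the precision.

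The stage means were fitted together for all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the stages share 1 estimate of the spread. A moderated F test compared the 5 stages, contrasts compared successive stages, and a cosine with a period of 12 months was fitted to the calendar month. All p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2 scale of the scaled intensity. On simulated data for each of the 5 successive comparisons, in which 200 of 8638 probes were changed, the fit recovered 41.8% to 59.7% of 1.5-fold changes. It recovered 68.7% to 89.6% of 2-fold changes and 93.9% to 97% of 4-fold changes. It made 5 to 9 false calls among 146 to 162 calls per comparison. Each comparison was simulated once with 66 or 67 probes per fold size, so that the ranges include variation between draws. In the real data a larger share of probes was called, so that recovery and false calls there can differ. A probe not well above background on any array of a stage has only a bound there. Its fold was taken as the brighter stage's mean against the mean, over the dim stage's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal.

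The files used here give probe identifiers and do not pair them with genes. The lists of genes fixed before the data were examined, and the rule for the genes to be named from them, therefore gave no result. In their place, the probes printed are the 2 with the largest rise and the 2 with the largest fall from spawning to post-spawning, among probes past the threshold, well above background on all arrays of both stages and with the same direction after leaving out any array. This replacement rule, and its limit to the first comparison, were chosen after the files were seen to hold no gene names. The fields within the probe names (an or un, s or as, sp or xh) are not explained in the sources used here.

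The arrays lie on 4 slides of 7 or 8 arrays each, and no recrudescence array is on slide 4. Slide was tested as a block and by leaving out each slide. With stage held, limma called 0 probes as different between slides, and 426 had an unadjusted p under 0.05. Other alternatives were another background correction (normexp with an offset of 50), quantile normalisation, centring on the median, scaling to the 5 brighter Agilent spike-in probes, other filters, array weights, an intensity trend and leaving out each array. The normexp alternative used median pixel intensities, since the files used here hold no mean signal column. The titles and the descriptions of the samples number the replicates differently, and the numbers in the text are those of the titles. Array brightness below means the array's 75th percentile relative to its spike-in probes, on the log2 scale.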

Results

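Testis RNA was compared among 31 male rainbow darters across an annual reproductive cycle, from spawning in May through the post-spawning stage in August, recrudescence in October, development in January and the pre-spawning state in March. The 75th percentile of the spot intensity averaged 3616 ± 535 (SD, n = 7) on the spawning arrays, 3798 ± 724 (n = 6) on the post-spawning arrays, 3848 ± 552 (n = 5) on the recrudescence arrays, 4026 ± 658 (n = 6) on the developing arrays and 3490 ± 332 (n = 7) on the pre-spawning arrays. Between 77.99% and 95.79% of the probes were well above background on each array. The median correlation of an array with the others of its stage lay between 0.9524 and 0.9825. Correlations across probes also reflect the differences in level between probes, and those between the means of 2 stages ranged from 0.8571 (post-spawning and spawning) to 0.9907 (spawning and pre-spawning), although means carry less noise than single arrays. The files used here do not pair probes with genes, so that groups of probes are described by their pattern over the stages.

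Most of the probes changed over the year. Of 8638 probes, 7565 (87.6%) differed among the 5 stages at an adjusted p under 0.05 in limma's moderated F test, and 1073 did not pass. Among the probes that passed, the highest and the lowest stage mean lay a median of 1.29 apart on the log2 scale, and 4828 probes spanned at least 2-fold and 951 at least 8-fold. The highest mean fell in the post-spawning stage for 3736 of them (49.4%), in developing for 1231 (16.3%), in spawning for 1169 (15.5%), in pre-spawning for 764 (10.1%) and in recrudescence for 665 (8.79%). The lowest mean also fell most often in the post-spawning stage, for 2240 probes (29.6%), followed by spawning with 1821 (24.1%).

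The post-spawning testis stood apart from the testis of every other month. The first principal component held 54.6% of the variance, and the post-spawning arrays had scores of 89.3 to 121 on it, whereas the highest score of any other array was 27.6. Against each of the other 4 stages, 2600 probes were higher in post-spawning testis and 1505 were lower. The corresponding numbers were 416 and 164 for developing, 86 and 146 for recrudescence and 46 and 72 for pre-spawning, and of the 181 such probes for spawning 67 (37%) were higher and the others lower. The second component (10.7%) separated developing testis, with scores of 21.1 to 64.6, from all other arrays, none of which exceeded 7.41.

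**Figure D1:**
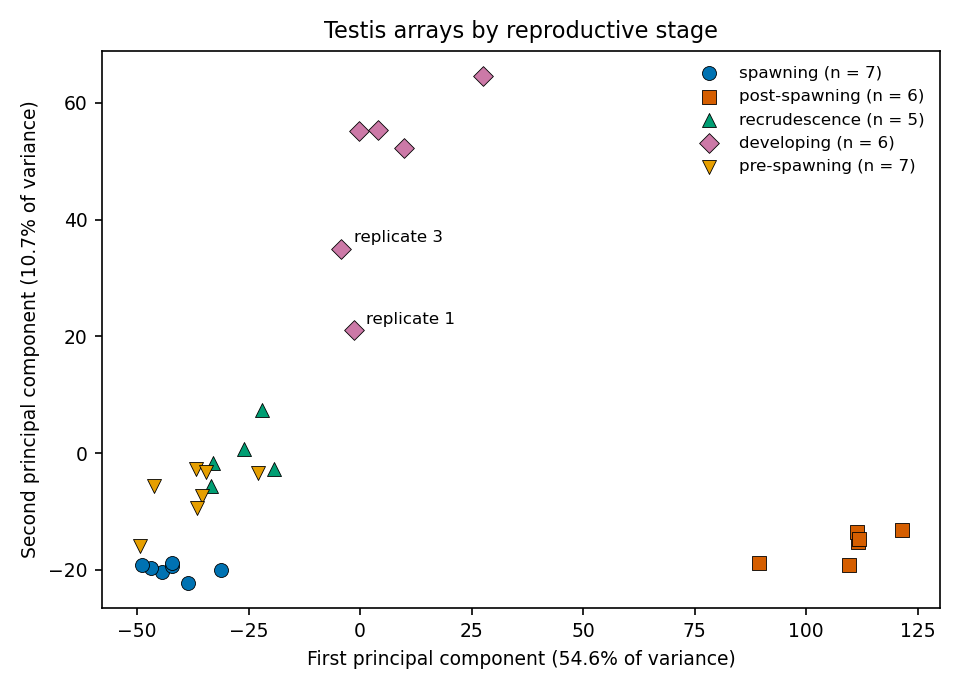
Scores of the 31 arrays on the first (x axis, 54.6% of variance) and second (y axis, 10.7%) principal component of the log2 signals of 8561 probes; each point is an array and colours and symbols mark the stages. The 6 post-spawning arrays lie at 89.3 or above on the first component, and the 6 developing arrays lie at 21.1 or above on the second, with replicates 1 and 3 nearest to the other stages.

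The first comparison asked what changes in the testis once spawning ends. From spawning to post-spawning, 4013 probes rose and 2431 fell, together 74.6% of those tested, and 2194 did not pass. At least 2-fold changes were found for 2364 rising and 1396 falling probes, and at least 8-fold changes for 349 and 323. Falls reached greater sizes than rises. Among probes well above background on all arrays of both stages, the largest fall was 242-fold and the largest rise 28.1-fold. A further 30 probes were well above background on all post-spawning arrays and on no spawning array, by a median of at least 11.1-fold, and 15 showed the opposite, by a median of at least 21.9-fold.

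On the means of all arrays, the largest fall was that of probe GT_EA516_an_as_xh_1291. Its log2 signal relative to the array's 75th percentile was 4.49 ± 0.35 (SD, n = 7) in spawning and -3.42 ± 2.07 (n = 6) in post-spawning testis, a log2 change of -7.92 ± 0.53 (SE) with an adjusted p of 7.21e-14. That SE uses the spread shared by all stages, which is smaller than that among the post-spawning arrays. Within slides the change ran from -10.7 to -5.2. The fall was transient, since the signal was 5.31 ± 0.31 (n = 5) in recrudescence, 4.44 ± 0.38 (n = 6) in developing and 4.08 ± 0.59 (n = 7) in pre-spawning testis. Probe GT_EA516_an_s_xh_3325 fell by 7.71 on the log2 scale (SE 0.34, adjusted p 1.04e-17), from 3.42 ± 0.36 to -4.29 ± 0.94. It stood at 3.30 ± 0.35 in recrudescence, at 1.56 ± 0.81 in developing and at 3.31 ± 0.44 in pre-spawning testis. On slide 3 alone this probe fell further than GT_EA516_an_as_xh_1291 (-5.71 against -5.2), so that their order depends on the arrays. The largest rises followed the opposite course. Probe GT_EA516_an_s_sp_847 rose by 4.81 (SE 0.31, adjusted p 3.47e-14), from -4.35 ± 0.62 to 0.46 ± 0.64, and was at -2.79 ± 0.64 in recrudescence, -3.63 ± 0.64 in developing and -3.89 ± 0.33 in pre-spawning testis. Probe GT_EA516_an_as_sp_4984 rose by 4.75 (SE 0.37, adjusted p 2.19e-12), from -4.62 ± 0.77 to 0.14 ± 0.56, and had come down to -2.25 ± 0.75 in recrudescence, -3.09 ± 0.85 in developing and -4.29 ± 0.49 in pre-spawning testis.

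**Figure D2:**
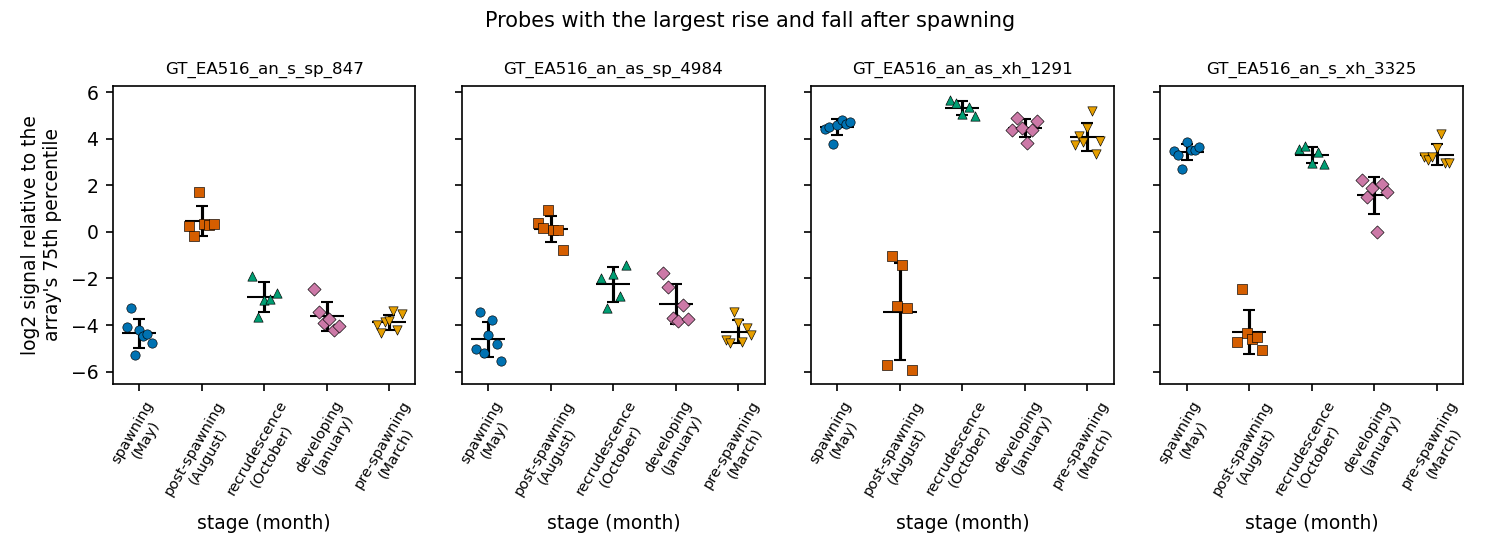
Log2 signal relative to the array's 75th percentile (y axis) of the 4 probes with the largest rises and falls from spawning to post-spawning, in each stage (x axis, with its month); points are arrays, and the black lines give the mean and SD of 5 to 7 arrays. The 2 probes on the left were highest and the 2 on the right lowest in post-spawning testis, where GT_EA516_an_as_xh_1291 averaged -3.42 against 4.49 in spawning testis.

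The balance between rises and falls depended on the scale. Under the 75th percentile scaling the median of all tested probes was 0.30 higher in post-spawning than in spawning testis on the log2 scale, against 0.13 with arrays centred on their median, where 3570 probes rose and 2829 fell (55.8% rising, against 62.3%). The 100 brightest probes held 36.7 ± 1.35% (SD, n = 6) of the summed signal in post-spawning and 30.4 ± 1.63% (n = 7) in spawning testis. With slide as a fixed block, 6468 probes changed. Of the probes called without a given slide, between 96.6% and 99.2% moved the same way on that slide.

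The second comparison followed the testis into recrudescence, when it begins to regrow. From post-spawning to recrudescence, 2018 probes rose and 4097 fell (70.8% of those tested), of which 1183 and 2122 changed at least 2-fold. The share of rising probes was 33% under the main scaling and 39.4% (2326 rising and 3585 falling) with arrays centred on the median. The largest rise among probes measured on all arrays of both stages was 426-fold and belonged to GT_EA516_an_as_xh_1291, and the largest fall was 18.8-fold. A further 21 probes were well above background on all recrudescence arrays and on no post-spawning array, by a median of at least 11.2-fold, and 41 showed the opposite, by a median of at least 7.93-fold. The change reversed that after spawning. Of the 2431 probes that had fallen after spawning 1852 rose again, and of the 4013 that had risen 3588 fell, so that 84.4% of the calls were reversed, while 31 probes moved the same way in both steps. Lists of these sizes drawn independently would share 568 and 1903 reversed probes and 2091 moving alike. Both comparisons use the same post-spawning arrays, which alone yields a negative correlation between the changes across probes. The correlation was -0.943 against -0.495 in simulations without an effect, and it averaged -0.919 when separate post-spawning arrays entered each comparison. Separate arrays remove the shared noise but not the shared stage mean, which can by itself give a negative correlation. The covariance was -2.32 against -0.0348 in the simulations. These hold no stage differences, and an effect on the post-spawning mean alone makes the covariance more negative.

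The return was not complete. Of the 6444 probes changed after spawning, 4418 no longer passed the threshold between recrudescence and spawning, 1705 still differed in the same direction and 321 differed in the opposite direction. Both comparisons subtract the same spawning arrays, which favours the same direction, and these counts were not set against their number without an effect. A probe that no longer passed can still differ. Directly compared, 1278 probes were higher and 1134 lower in recrudescence than in spawning testis (1167 and 1266 with arrays centred on the median), and this pair of stages was added after the data were examined. With slide as a fixed block 6016 probes changed from post-spawning to recrudescence. On the 3 slides that hold both stages, 97.4% to 97.8% of the probes called without a slide moved the same way on it.

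The third comparison covered the step from recrudescence to developing testis in winter. It showed 2329 rising and 1352 falling probes, 42.6% of those tested, of which 463 and 512 changed at least 2-fold. Large changes went mostly upward, since 63 probes rose and 5 fell at least 8-fold. The largest rise was 30.3-fold and the largest fall 9.39-fold among probes measured on all arrays of both stages. Scaling to the spike-in probes in place of the 75th percentile left 1638 probes, of which 75.3% rose against 63.3%, while 56% (1914 rising and 1504 falling) rose with arrays centred on the median and 56.3% with quantile normalisation. Developing replicates 1 and 3 differed from the other 4 developing arrays, and 3718 probes changed without both under the main scaling. With slide as a fixed block 3666 probes changed. Without slide 3 the count was 2185, and 98.8% of those probes moved the same way on slide 3. The shares on the other 2 slides with both stages were 95.8% and 89.5%. Of the calls from post-spawning to recrudescence 43.2% were reversed in this step. Of the 4097 probes that had fallen 1630 rose, and of the 2018 that had risen 1011 fell, where independent lists would share 1105 and 316. In both steps 352 moved alike, against 1185 for independent lists. Such lists ignore the recrudescence stage that both steps share. The correlation of the 2 changes across probes was -0.495, no stronger than the -0.537 in simulations without an effect, and -0.443 on average with separate recrudescence arrays. The covariance was -0.56 against -0.0423. Since the simulations hold no stage differences, an effect on the shared recrudescence mean alone makes the covariance more negative. It therefore adds no evidence of a reversal.

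The fourth comparison, from developing to pre-spawning testis, showed 1666 rising and 2859 falling probes (52.4% of those tested), of which 405 and 945 changed at least 2-fold and 1 and 63 at least 8-fold. No probe was gained, and 17 that were well above background on all developing arrays were so on no pre-spawning array, by a median of at least 3.13-fold, with 16 of them past the threshold. Many calls of the winter step were followed by a call in the opposite direction. Of the 2329 probes that rose into the developing stage 1658 fell, and of the 1352 that fell 901 rose, together 69.5% of the calls, where independent lists would share 771 and 261. The correlation of the 2 changes across probes was -0.72, against -0.491 in simulations without an effect. With separate developing arrays it averaged -0.591 (-0.678 to -0.483 over 20 splits). The covariance was -0.424 against -0.0348 in the simulations. These hold no stage differences, and an effect on the developing mean alone makes the covariance more negative. Both steps contain the developing mean, which alone can give a negative correlation and more reversals than independent lists, also with separate arrays. Compared directly, 2566 probes (29.7%) differed between pre-spawning and recrudescence, against 42.6% and 52.4% in the 2 steps. This pair was added after the data were examined. The share of rising probes from developing to pre-spawning was 36.8% under the main scaling. It was 47.3% (2088 rising and 2327 falling) with arrays centred on the median and 9.19% (342 and 3380) with spike-in scaling. Spike-in scaling adds each array's brightness to its values. Brightness averaged -0.79 ± 0.46 (SD, n = 6) in developing, raised by replicate 3 (0.11), and -1.18 ± 0.27 (n = 7) in pre-spawning testis. The share without replicate 3 was not computed under that scaling. Under the main scaling the count was 4418 without developing replicates 1 and 3, and 4357 with slide as a fixed block. Of the probes called without a slide, 91.4% to 97.5% moved the same way on it.

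The last comparison set the spawning testis of May 2011 against the pre-spawning testis of March 2012, so that it closes the cycle across collection years. It showed the fewest changes of the 5, with 438 probes higher and 379 lower in spawning testis, 9.46% of those tested, and 65 and 46 at least 2-fold. The stage means correlated at 0.9907 across probes, against 0.8571 between post-spawning and spawning. No probe was gained or lost by the background criterion. The count was sensitive to the arrays used. It was 536 without spawning replicate 1, 503 without pre-spawning replicate 7 and 67 without slide 2, which holds both of these arrays. The balance of directions depended on the scale. More probes were lower than higher with arrays centred on the median (381 higher and 470 lower), quantile normalisation (382 and 439), normexp (330 and 390) and the authors' table (391 and 432), while spike-in scaling left 105 probes, 98 higher and 7 lower. With slide as a fixed block 756 probes changed, and 77.1% to 95.5% of the probes called without a slide moved the same way on it.

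**Figure D3:**
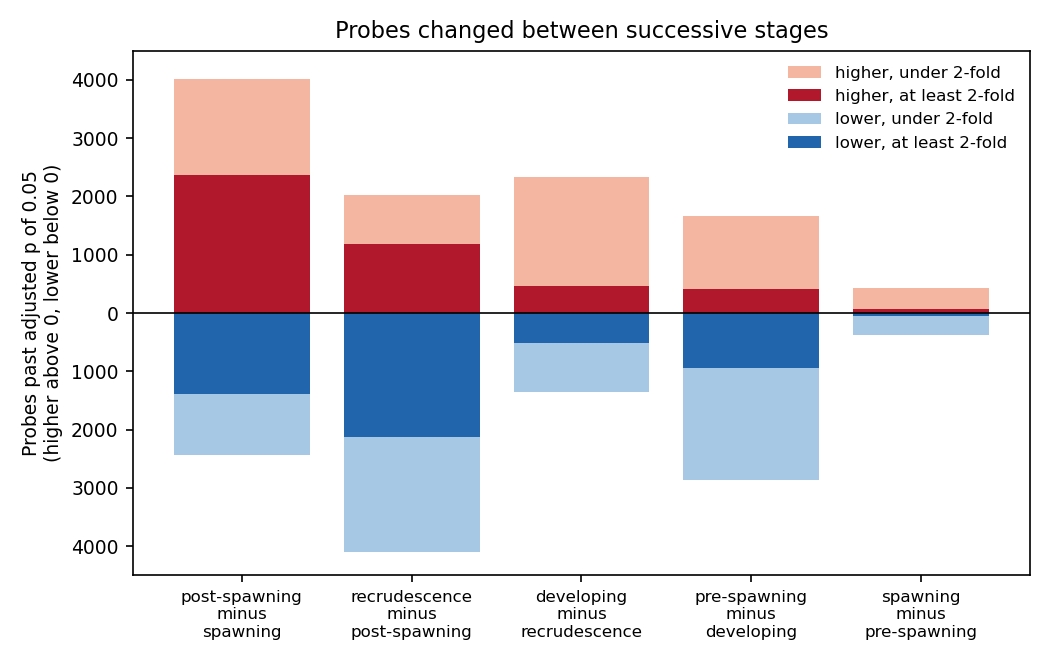
Number of probes past an adjusted p of 0.05 (y axis, higher above 0 and lower below 0) in each comparison of successive stages (x axis), with darker parts for changes of at least 2-fold. The bars run from 4013 higher and 2431 lower probes in post-spawning against spawning to 438 and 379 in spawning against pre-spawning.

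Over the whole cycle the most frequent course, shared by 1041 probes (12.1%), was to rise after spawning, fall in recrudescence, rise in the developing stage and fall again before spawning. Another 1018 probes (11.8%) rose after spawning, fell in recrudescence and passed no later threshold. The mirror image of the most frequent course, with a fall after spawning, a rise in recrudescence, a fall and a rise, was followed by 656 probes (7.59%). Successive comparisons share the arrays of a stage, which favours such alternating courses, and these counts were not set against their number without an effect. No change between successive stages was called for 893 probes (10.3%).

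The title of the series asks about rhythms of expression over the year. A cosine with 1 peak in 12 months passed the threshold for 5698 probes (66%), of which 5650 also differed among stages, while 1915 probes differed among stages without a cosine call. Months were numbered from 1 for January, with 0 and 12 both for December. Peaks fell between 6 and 9 for 30.1% of the probes with a cosine and between 9 and 12 for 26.9%. They fell between 0 and 3 for 24.3% and between 3 and 6 for 18.8%. The cosine held a median of 48.5% of the variance between stages in the probes that differed among stages, against 49.9% in the median of other orders of the months over the stages (18.3% to 76.3%), which were tried after the data were examined. The cosine count fell to 3382 with spike-in scaling and to 3249 without slide 4.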

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

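Apart from the regroupings of the arrays, the tests in this part were chosen only after the results were seen. An array was singled out when the gap between it and its nearest neighbour took up more of its stage's range than Dixon's critical value for 95% allows. Over 15 measures and 5 stages, 75 groups were examined and 14 stood out, 4 of them among the 30 groups of the 6 measures of whole arrays. The other 10 came from the 4 printed probes and the 5 groups of probes below (6 of the 10), which were chosen for their changes and their spread, so that a chance rate of 1 in 20 does not apply to them. To find transcripts that differ between fish of a stage, the 150 probes with the largest spread within stages were grouped by their correlation, and 5 groups of at least 5 probes emerged, with 33, 32, 10, 8 and 5 probes.

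The 6 post-spawning arrays stood apart from all others, and 6444 probes changed from spawning to post-spawning. Among 100 regroupings of the arrays of both stages, the real one included, 1 gave as many probes, and the highest of the others gave 6053. That regrouping exchanged all 6 post-spawning arrays for spawning arrays, so that it is nearly the mirror image of the real one and keeps most of its difference. Scaling of the arrays would need the count to collapse under another scale, but the fewest probes under quantile, median and spike-in scaling were 5093, with at least 2285 in each direction. Slide was also argued against, since at least 96.6% of the probes called without a slide moved the same way on it, and so was array brightness, since all 5 post-spawning arrays within the brightness range of the spawning arrays lay beyond every other stage on the first component. A change in the testis with the end of spawning, including a change in its mix of cell types, may underlie the difference as a hypothesis. Season stays confounded with it, and without gene names no cell type could be examined.

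Developing replicates 1 and 3 stood apart from the other 4 developing arrays, with median correlations to their stage of 0.9524 and 0.9617 against 0.9764 or more. A wrong stage label stays open. By plain distance over all probes, replicate 1 lay only 0.06 (log2) nearer to its own stage than to another. Replicate 3 lay 0.157 nearer, against a margin of 0.1 set for both. The other 4 developing arrays lay 0.363 to 0.502 nearer to their own stage. Of all 31 arrays 9 lay under that margin, 4 of them under replicate 1 and 1 (pre-spawning replicate 5) nearer to another stage than to its own. Apart from replicate 1, these were spawning or pre-spawning arrays nearest to each other's stage. The means of those stages correlated more than those of any other pair (0.9907). On 1 of 3 principal components fitted without both arrays, a measure chosen after those distances were seen, each lay at least 5.66 SD from each of the other 4 stages, but replicates 1 and 3 also lay 9.09 and 6.46 SD from the other 4 developing arrays, so that this measure rejects the given label as well. Independent noise of single arrays would not be shared between them, yet their differences from separate pairs of the other developing arrays, so that no array enters both, correlated at 0.503 across probes on average (0.47 to 0.523 over the 6 ways to form the pairs), against averages of at most 0.239 for any other pair of developing arrays. For every other pair the reference arrays include replicate 1, replicate 3 or both, which can move its correlation. Against the mean of the same 4 arrays the correlation of replicates 1 and 3 was 0.607, part of which comes from the shared arrays. A slide effect was argued against by the correlation of their differences with arrays of other stages on their slides, which was 0.204 at most. Replicate 1 lay on slide 2 and replicate 3 on slide 1, so that no single slide is common to both. A state of these testes between developing and another stage, or RNA from other cells, may explain the pattern and was not tested. The SD of the negative-control signal was 9.65 on replicate 1 and 3.32 on replicate 3, and 31 and 18 spots carried outlier flags. Brightness was -0.83 and 0.11, the latter the highest of all arrays. Whether array quality contributes was not tested.

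A group of 10 probes varied up to 69.8-fold between arrays, and 0 of them differed among stages in limma's F test (0 at an unadjusted p under 0.05). Its mean level followed array brightness over the 31 arrays (Pearson's r = -0.906, Spearman's rho = -0.917, permutation p = 1e-05 each, the smallest that the permutations can give, and 5e-05 after adjustment over the 5 groups of probes). The correlation was -0.907 with stage means removed, -0.862 without the 2 arrays of most extreme brightness, and -0.898, -0.881, -0.942 and -0.969 within slides 1 to 4. Scaling alone would give a slope of -1, and the slope was -3.67 ± 0.32 (SE). Over all 8561 probes with complete values, 154 fell with brightness at a correlation beyond -0.8 within stages, and 7 rose beyond 0.8. Of 100 orders of brightness within stages, only the real order gave as many falling probes, and the others gave 0 at most. These orders cannot tell whether scaling alone gives the 154, since each level is relative to the array scale that brightness also contains. Shuffling breaks that link, and the slopes of the 154 probes were not compared with -1. Of the 154 probes, 103 (66.9%) carry "un" in their names against 27.3% of all probes. The amount or the integrity of RNA on an array relative to the spike-in probes is a candidate explanation, with no measure of either to test it. With brightness as a covariate the 7 counts of probes in the report moved by less than 1.5 times.

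Developing replicate 3 had a brightness of 0.11 against -0.83 for the nearest developing array, and the 10-probe group averaged -5.08 on it against -1.38. The 75th percentile of pre-spawning replicate 3 was 4187 against 3544 for the next array, and post-spawning replicate 4 had 95.79% of its probes well above background against 90.31%. Post-spawning replicate 2 had a first component score of 89.34 against 109.5, the closest of its stage to the other stages. It also had a level of -2.438 for GT_EA516_an_s_xh_3325 against -4.333, and a mean of -4.37 for the 8-probe group against -5.02. Probe GT_EA516_an_s_sp_847 stood at 1.692 in post-spawning replicate 3 against 0.3515, GT_EA516_an_as_xh_1291 at 3.752 in spawning replicate 3 against 4.417, and GT_EA516_an_s_xh_3325 at -0.00517 in developing replicate 4 against 1.505. The 33-probe group averaged -5.30 in spawning replicate 2 against -6.93, and the 8-probe group -0.192 in spawning replicate 6 against -4.14. The 5-probe group averaged 3.36 in pre-spawning replicate 2 against -2.88, and -5.42 in post-spawning replicate 5 against -4.24.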

How the results depend on the processing

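The alternatives were fixed before the data were examined, except spike-in scaling, brightness as a covariate, leaving out a slide, leaving out developing replicates 1 and 3 together, and the use of median pixel intensities for normexp. The count of probes differing among stages stayed within 1.5 times its main value under all 20 alternatives (6046 to 7667) and without any array (7467 to 7584). Requiring at least 2-fold left 3760, 3305, 975, 1350 and 111 probes in the 5 successive comparisons, in their order, as fewer probes can pass. Spawning against pre-spawning (817 probes) was the least stable, with 221 at an adjusted p under 0.01, 540 from the arrays of both stages alone, 105 with spike-in scaling, 536, 67 and 308 without slides 1, 2 and 4, and 503 (without pre-spawning replicate 7) to 922 without an array. It was 536 without spawning replicate 1. The settings without arrays or slides test on fewer arrays by construction, and the cause of the other changes was not tested. Spike-in scaling left 1638 probes from recrudescence to developing and 3382 with a cosine, without slide 3 the former count was 2185, and without slide 4 the latter was 3249. The other alternatives for these counts, including the authors' table and both developing replicates left out, stayed within 1.5 times. The 4 printed probes kept their direction and passed the threshold in each alternative that was tested. They were chosen as the largest changes with the same direction without any array, which largely fixed this outcome and does not extend to other probes. Within slides, GT_EA516_an_as_xh_1291 fell and the other 3 probes kept their directions on all 4 slides.

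The replicate numbers do not pair the arrays, since arrays of different stages with the same number deviated together at a mean correlation of -0.0032 (title numbers) and 0.0167 (description numbers), and 3 and 4 of the 31 arrays correlated best with their own number. For arrays of different stages on the same slide the mean correlation was -0.0013. On this measure 13 of the 31 arrays correlated best with an array of their own slide, which was not tested against chance. With the title number as a replicate block 7477 probes differed among stages and 6420, 6078, 3543, 4445 and 708 changed in the successive comparisons, and 5093 followed a cosine. With the description number these counts were 7556, then 6393, 6124, 3621, 4458 and 810, and 5022. No count of calls moved by 1.5 times. The tests of gene lists and their alternatives, and those of named genes, were not run because no probe is paired with a gene. Probes below background on either side of a comparison have only bounds, and the 403 dimmest were not tested.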

Other observations

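The tests in this part were chosen only after the results were seen, except the regroupings of the arrays. A group of 32 probes with a large spread within stages marked 4 of the 6 developing testes. Its mean log2 level was between -2.19 and -1.30 in developing replicates 2, 4, 5 and 6, and at or below -4.96 on each of the other 27 arrays, including developing replicates 1 and 3. A group of 33 probes was highest in pre-spawning replicates 2, 3 and 4 and developing replicates 1 and 3 (-3.90 to -2.72) and at most -4.84 elsewhere. The 5-probe group, which includes 2 of the 18 custom probes of the array, reached 3.36 in pre-spawning replicate 2, 0.45 in developing replicate 1 and -1.27 in developing replicate 3. It was -2.88 or lower on the other 28 arrays. The 8-probe group ranged from -5.40 to 1.31, with 16 arrays at or below -3.91 and 15 at or above -2.61. Probes were kept when well above background on at least 5 arrays. The low levels of these groups may therefore lie near background, which was not examined.

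Of the 17 custom probes tested, 16 differed among stages. After spawning 9 rose and 4 fell, in recrudescence 3 rose and 8 fell, in the developing stage 4 rose and 2 fell, before spawning 2 rose and 8 fell, and 0 differed between spawning and pre-spawning by limma's adjusted p, with 6 at an unadjusted p under 0.05.

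Comparisons of stages that do not follow each other, added after the data were examined, found 5453 probes between developing and post-spawning, 6382 between pre-spawning and post-spawning, 5009 between developing and spawning, 2566 between pre-spawning and recrudescence and 2412 between recrudescence and spawning.

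Regroupings of the arrays tested whether a random assignment of arrays to stages gives counts as large as those in the report. With 100 regroupings the share cannot fall below 1 in 100, and the single collection per stage is not addressed. For the cosine, the regroupings test any difference among stages and not the calendar order. For each of the 7 counts, 1 of 100 regroupings, the real one, gave as many probes. The highest of the others was 2 probes against 7565 among the 5 stages, 1 against 5698 for the cosine, 5621 against 6115 from post-spawning to recrudescence, 3198 against 3681 from recrudescence to developing, 3139 against 4525 from developing to pre-spawning and 17 against 817 between spawning and pre-spawning. In the highest of the regroupings of post-spawning with recrudescence, and of recrudescence with developing, 5 arrays of the later stage had been exchanged, and 1 in that of developing with pre-spawning, so that these were near mirror images or near copies of the real grouping.

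A cosine call may be read as a yearly rhythm, and whether the calendar order of the stages matters to it was tested as a hypothesis. The 5 months were dealt to the stages in 100 orders, the calendar order included, and 54 gave at least as many probes as the 5698 of the calendar order. The others ranged from 1594 to 6671, with a median of 5895. By this count, the calendar order was no better than other orders, and a repeat of the months in another year was not analysed here.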
